A study of Mus musculus with 11 samples.

How the data were processed

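The study sequenced poly(A)-selected, strand-marked RNA libraries of Notch1-IC leukaemias as single reads of 50 bases, per the labels' protocols; its design text also allows for depletion of ribosomal RNA in place of poly(A) selection. Base calling used CASAVA, alignment used TopHat and the genome build was mm9, per the submitters' processing notes, which give no versions. The annotation, the counting tool and the strand used in counting are not given in the sources used here. The authors compared knockout with wild-type by DEGseq, per the series' design text.

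The data used were 1 table made by the authors with DEGseq, with 37224 gene rows, each named by an Ensembl identifier and a symbol. Its 2 value columns hold whole read counts, pooled by the authors over libraries of a genotype, per the file headers and the values; which of the 11 samples entered each pool, and whether repeat runs were added, is not given in the sources used here. The first value column was taken as the knockout pool and the second as the wild-type pool, from the order of the genotypes in the table's title and the usual order of DEGseq output; the level of the targeted gene was then checked. The table also holds log2 fold changes deposited by the authors before and after normalization, which differ by 0.0211, the log2 ratio of the column totals, and in which a count of 0 was replaced by 0.5. A score per gene, the z value of the authors' DEGseq test per the file headers, was not used further. The p-values and the 2 kinds of q-values in the authors' deposited table come from their DEGseq test; the Benjamini-Hochberg q was used, with the Storey q and a p under 0.001 as alternatives. A fold change was given by the authors for 20904 genes, and the 2477 rows with a count but no fold change had a combined count of at most 4. Rows with no count in either pool numbered 13843. The number of columns with per-sample values was 0, so tests across samples (a count model, a block for the replicate number, leaving out samples) were not run.

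From these counts, CPM values were computed with the total of the gene rows as depth, and log2 ratios of knockout over wild-type with a pseudocount of 0.5 counts in each pool. The exact 95% interval of a ratio was taken from the Clopper-Pearson interval of the knockout share of the combined count. It covers counting error only and holds no difference between animals. It treats reads as independent molecules, which they are not, so it can be too narrow even for counting error. A gene was called higher or lower with a combined count of at least 100, a log2 ratio of at least 1 in size and an interval without 0. A count of 0 would allow up to 3 counts, which is 0.0282 CPM in the knockout pool and 0.0278 in the wild-type pool. Values near 100 combined counts are less precise than those of deeper genes.

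The gene lists were fixed before the data were examined: 29 lists of pathways, complexes, leukaemia genes, other cell types, sex-linked genes and RNA classes. Members were matched by Ensembl identifier through the GENCODE M21 annotation (GRCm38), then by a symbol borne by 1 row. Of the genes with at least 100 counts, 98.4% matched that annotation by identifier; 267 symbols stand for more than 1 identifier. Coordinates printed are from GENCODE M21 and not from mm9. A member was measured with a combined count of at least 20. Each list's median log2 ratio was placed among 10000 random lists of the same size, drawn from the same 20 bins of mean expression. The named genes were also set before the data were examined: Kdm6a, Uty and Kdm6b; the 12 highest and 12 lowest log2 ratios among genes with at least 100 combined counts and a mean of at least 5 CPM, without unnamed gene models and small RNAs; and up to 2 highest and 2 lowest members of each list with at least 100 counts, plus called members. Further list members were named to show abundant or well-known genes and were chosen after their values were seen. A few called list members are not reported here by name.

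The calls and intervals were tested on simulated Poisson counts for the knockout against the wild-type pool, with 13858 genes. Of 100 genes changed by a log2 of 1.5 and 100 changed by a log2 of 2, 100% were recovered at each size, 0 unchanged genes were called and the intervals covered 94.7% of the true ratios. The changed genes were drawn from genes well above the minimum of 100 combined counts, so recovery near that minimum was not tested. This test holds no biological spread.

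Other settings, chosen before the data were examined, were TMM, median of ratios and upper quartile scaling, a pseudocount of 5, other count and fold minimums, calls without the other cell type lists, and the mean or a higher count minimum for the lists. Added after seeing the data were a depth without mitochondrial and erythroid genes, calls without sex-chromosome genes and T cell receptor segments, the ribosomal protein list without kinases, and the tests on chromosomes. Chromosome medians used genes with at least 100 combined counts, 12 windows of equal gene number along the chromosome, 1000 random lists per chromosome, 10000 bootstrap draws over genes and the GC content of the longest GENCODE M21 transcript in 5 bins. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 for the TMM and upper quartile factors.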

Results

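RNA-seq was used to compare T cell acute lymphoblastic leukaemias (T-ALL) that arose in mice from blood progenitors with or without Utx. Utx, listed as Kdm6a, is an X-linked demethylase that removes the repressive methyl marks of histone H3 lysine 27. Progenitors positive for the cKit receptor carried an activated intracellular form of Notch1 (Notch1-IC) on a retrovirus, and leukaemia was taken from bone marrow or spleen of the recipients. The labels list 11 samples, 5 from Utx knockout and 6 from Utx wild-type donors. Of the knockout samples 2 came from bone marrow and 3 from spleen, and of the wild-type samples 2 came from bone marrow and 4 from spleen; 1 marrow sample of each genotype and 1 wild-type spleen sample were repeat runs. The knockout donors were male and the wild-type donors were of either sex, per the labels.

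The values used were 1 pooled count per gene and genotype, so that 106445530 counts stood for the knockout pool and 108015222 for the wild-type pool. A count was present for 21374 genes in the knockout pool and for 22256 in the wild-type pool, and 13833 genes had a combined count of at least 100. No spread between animals could be computed from pooled counts, so no difference given here has a replicate check, and a pool does not show whether all of its tumours or a single tumour gave a gene's counts. The intervals are exact 95% Clopper-Pearson intervals and cover counting error only; the median half-width on the log2 scale was 0.54 for genes with a combined count of 100 to 200 and 0.049 for those with 10000 to 20000. A gene is called higher or lower in the knockout pool where its combined count was at least 100, its depth-scaled values differed by at least 2-fold and the interval excluded no difference.

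Utx itself was lower in the knockout pool. Kdm6a (ENSMUSG00000037369, chromosome X, 18162575 to 18279936 on the plus strand, GRCm38 coordinates of the GENCODE M21 annotation) had 1115 counts in the knockout pool and 6299 in the wild-type pool, or 10.5 against 58.3 counts scaled to depth (CPM, relative to the total of the gene rows). Its log2 ratio was -2.48 (95% interval -2.57 to -2.38), so that the knockout pool held 18.0% of the wild-type level, over the whole gene and not over the deleted part. Uty (ENSMUSG00000068457, chromosome Y, 1096861 to 1245759), the Y-linked relative of Utx, was higher at 15.6 against 1.82 CPM, a log2 ratio of 3.09 (2.88 to 3.32). Kdm6b (ENSMUSG00000018476, chromosome 11, 69398508 to 69413675), the other demethylase of this mark, was at 63.6 against 39.4 CPM, a log2 ratio of 0.69 (0.64 to 0.75) that stayed under the 2-fold minimum. The 3 genes together had a median of 0.69, which is the ratio of Kdm6b alone, at percentile 97.8 of random lists of like expression. This percentile was 90.0 when the mean, 0.44, was used in place of the median.

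Several genes that mark sex differed between the pools more than Utx did. Xist, the RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), had 75 counts in the knockout pool and 21976 in the wild-type pool, a log2 ratio of -8.16 (-8.52 to -7.85). Tsix overlaps Xist on the other strand and stood at -7.39; the strand used in counting is not given in the sources used here, so the reads of these 2 genes cannot be told apart. The Y-linked genes Kdm5d, Eif2s3y and Ddx3y were higher in the knockout pool, at log2 ratios of 4.24, 3.10 and 2.65. Summed with Uty, the Y-linked genes in the wild-type pool reached 12.7% of their level in the knockout pool. The X-linked partners Eif2s3x, Ddx3x and Kdm5c had log2 ratios of -0.58, -0.54 and 0.14, and none was called. Over the 9 measured genes of the sex-linked list, 4 were higher, 2 lower and 3 neither; the median was 0.14, at percentile 93.8, while the mean had the other sign at -0.38. Genotype and sex markers thus differed together between the pools. The X-linked partners, at -0.58 to 0.14, lay far from Kdm6a at -2.48, which argues against sex alone for the ratio of Kdm6a. An exact split of that ratio between genotype and sex is not possible. Uty, at 3.09, lay within the range of the other Y-linked genes, 2.65 to 4.24, so its ratio cannot be told apart from sex.

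**Figure D1:**
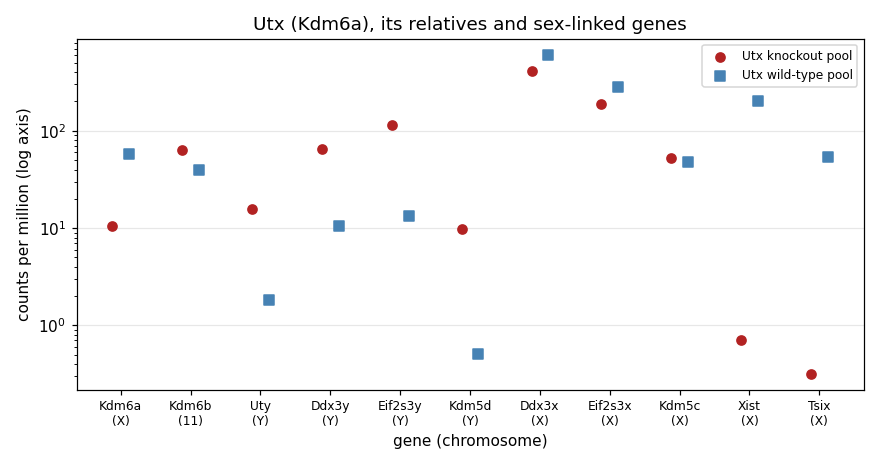
Depth-scaled counts (CPM, log axis) of Utx (Kdm6a), its relatives and sex-linked genes in the Utx knockout pool (circles) and the Utx wild-type pool (squares), with the chromosome of each gene under its name. Kdm6a was at 10.5 against 58.3 CPM, Xist was the gene with the widest gap, and the Y-linked genes were higher in the knockout pool.

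More genes were higher than lower in the knockout pool. Of the 13833 genes with enough counts, 1551 (11.2%) were higher and 741 (5.36%) were lower by at least 2-fold. The authors' deposited table, from the DEGseq test on pooled counts, called 1556 genes higher and 746 lower at an adjusted p under 0.05 with the same fold and count minimums, and 2292 genes were called in the same direction by both. Both sets of calls rest on the same pooled counts, scaling by totals and minimums, so their overlap is no independent check. Without a fold minimum the order turned: the authors' deposited table then held 5057 genes higher and 6387 lower. Over all counts and folds, 14173 genes passed an adjusted p of 0.05 in the authors' deposited table, which is 67.8% of the genes given a fold change there. That test compares these pools of reads and carries no spread between tumours as far as the table shows. The median log2 ratio over the 13833 genes was -0.07 with the total as depth and with upper quartile scaling. It was 0.01 with TMM and 0.03 with a depth that leaves out mitochondrial and erythroid genes, so its sign depends on the scaling. The order without a fold minimum was not recounted under other scalings.

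The 12 genes with the largest ratios among named genes with a mean of at least 5 CPM included several that the wild-type pool hardly held. Robo1, an axon guidance receptor (ENSMUSG00000022883, chromosome 16, 72308306 to 73046095), had 5819 counts in the knockout pool and 4 in the wild-type pool, a log2 ratio of 10.36 (9.17 to 12.40). Dnahc9, an axonemal dynein, had 3112 against 3 counts, a log2 ratio of 9.82 (8.49 to 12.32). The adrenergic receptor gene Adra2a was at 143 against 0.29 CPM, a log2 ratio of 8.94 (8.45 to 9.52). Serpinb8, a protease inhibitor, stood at 8.83 (8.11 to 9.79), and Gabra4, a GABA receptor subunit, at 8.78 (7.24 to 12.14). Log2 ratios of 7.34, 7.32, 6.94 and 6.79 were found for the homeobox gene Meis2, Sytl2, the retinol transporter gene Stra6 and Moxd1. H19, an imprinted noncoding RNA, was at 68.0 against 0.67 CPM, a log2 ratio of 6.66 (6.34 to 7.03). The T cell receptor segment Trbv5 stood at 6.49 and Rai14 at 6.38.

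Among named genes with a mean of at least 5 CPM, the largest negative ratios after Xist and Tsix were those of the T cell receptor segments Trbv15 and Trdv1. Trbv15, a variable segment of the beta chain, had 1148 counts in the knockout pool and 58956 in the wild-type pool, a log2 ratio of -5.66 (-5.75 to -5.58). The delta chain segment Trdv1 stood at -5.64 (-5.90 to -5.39) and Trbv30 at -3.59 (-3.84 to -3.35). Ptk7, a receptor with an inactive kinase domain, was at 0.90 against 25.3 CPM, a log2 ratio of -4.80 (-5.12 to -4.52). The carboxypeptidase gene Cpe, the uroplakin gene Upk1b and Saa3, an acute-phase protein gene, had log2 ratios of -4.59, -4.51 and -3.90. Ldoc1l, the guanine nucleotide exchange factor gene Trio and the sodium channel subunit gene Scn4b followed at -3.83, -3.74 and -3.69.

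**Figure D2:**
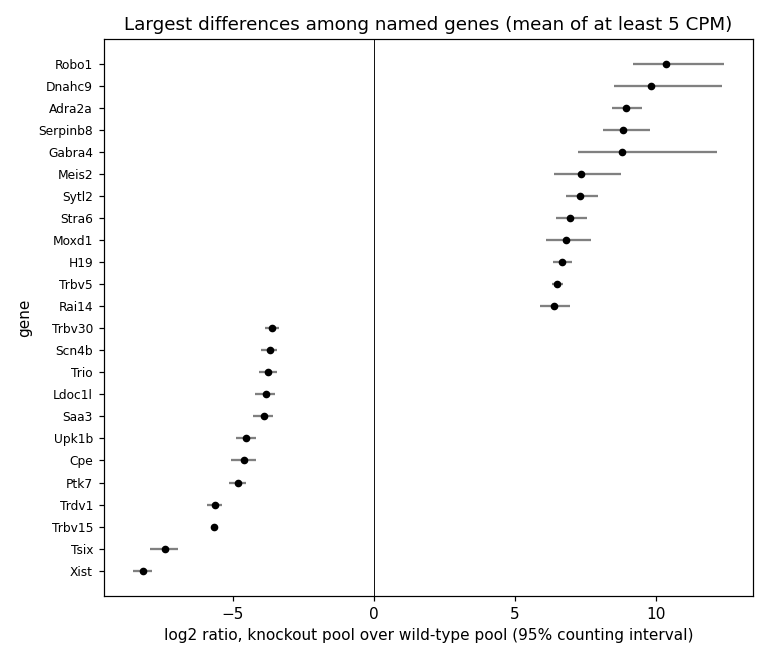
Log2 ratio of the knockout pool over the wild-type pool for the 12 largest and the 12 smallest ratios among named genes with a mean of at least 5 CPM (points), with the exact 95% counting interval (bars). Of these genes Robo1 was highest at 10.36 and Xist lowest at -8.16.

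A panel of 29 gene lists was compared with 10000 random lists each, matched in size and expression. The medians of 14 lists lay above the central 95% of their random lists, 1 lay below and 14 lay within. By chance 1.45 would lie outside if the lists and the genes in them were independent. Lists share members, as 11 of the 25 measured T-ALL oncogenes are also in another list. The excess over 1.45 is therefore no measure of how many lists truly differ. These percentiles describe the pools and are no test of the genotype.

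NOTCH1 target genes lay within their random lists as a group. Of the 25 measured targets 6 were higher, 1 was lower and 18 were neither, with a median of 0.06 at percentile 92.4. The higher members were Il7r, the interleukin 7 receptor (log2 ratio 2.49, 2.45 to 2.53; 318 against 56.7 CPM), Hey1 (2.47), Rhou (2.01), Il2ra (1.28), Fjx1 (1.14) and Trib2 (1.07). The lower member was Hes5, at -1.53 on 39 against 115 counts, and the feedback inhibitor Nrarp was at -0.67. Notch1, whose reads here cannot be split from those of the transduced form, was at -0.22 and the target Hes1 at 0.34.

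T cell and thymocyte genes had a median of 0.28, at percentile 100 after rounding, with 7 of 35 higher, 1 lower and 27 neither. The homing and egress receptor genes Ccr7 and S1pr1 were higher at log2 ratios of 2.64 and 2.03. So were Rag1 (1.60) and Rag2 (1.09), which make the recombinase of receptor rearrangement, and Cd7 (1.48) and Il2ra. Thy1 was lower at -1.06, a call that ended under other scalings, where it was -0.98 with TMM and -0.99 with the median of ratios. The co-receptor genes Cd4 and Cd8a were at -0.41 and -0.15, Cd3e at -0.03 and Cd6 at -0.72. Erythroid and granulocyte and monocyte markers were also higher in the knockout pool, with medians of 0.55 and 1.04.

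Genes known as T-ALL oncogenes stood higher as a group, with a median of 0.28 at percentile 99.9. Of 25 measured, 5 were higher and none was lower: Il7r, Lyl1 (1.72), Hoxa9 (1.39), Ccnd2 (1.28) and Stat5a (1.26). Tal1 was at 0.64, Myc at 0.28, Jak3 at -0.85 and Ccnd3 at -0.39. Several of these genes are also expressed in myeloid and erythroid cells, whose lists had medians of 1.04 and 0.55. Genes known as tumour suppressors in T-ALL had a median of 0.02 at percentile 94.7, within the random lists, with 3 of 28 higher and none lower. Among the higher ones were Cdkn2b (2.53, 2.11 to 2.99), which encodes a cyclin-dependent kinase inhibitor, and Gata3 (1.11). Rpl5 and Cdkn2a were at -0.95 and -0.83, Fbxw7 at -0.61 and Suz12 at -0.45.

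Stem and progenitor genes had a median of 0.98 at percentile 99.9, with 5 of 17 higher and none lower. The transcription factor gene Erg (3.19) and the surface receptor gene Cd93 (2.56; 7355 against 1263 counts) were highest, followed by Lyl1, Kit (1.52) and Gata2 (1.46). Flt3 was at -0.77 and Lmo2 at 0.10. Megakaryocyte and stromal markers moved the same way, with medians of 0.98 and 1.13. Of 39 Hox genes 11 were measured, and 4 were higher and none lower: Hoxa7 (3.13), Hoxb4 (1.5), Hoxa9 and Hoxc9 (1.37). Their median was 1.99 at percentile 100 after rounding. With the 4 members that had at least 100 counts alone, the median was 1.44 and the percentile 97.4, inside the central 95% of random lists.

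The complexes that write the marks Utx acts on or beside lay within their random lists. Of 30 Polycomb subunit genes, 1 was lower, Pcgf5 at -1.25 (-1.35 to -1.14), and none was higher, with a median of -0.09 at percentile 51.6. Phf19 was at -0.99, Ezh2 at 0.46, Mtf2 at 0.55 and Cbx2 at 0.56. None of the 15 genes of the MLL/COMPASS complexes was called, and their median was -0.20 at percentile 23.6. Mll2, listed elsewhere as Kmt2d, had the largest ratio at 0.82, and Psip1 and Wdr5 were at -0.54 and -0.53.

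Cell cycle genes had a median of -0.26 at percentile 6.9, and none of 30 was called. Bub1b was at -0.82, E2f1 at -0.72, Mki67 at -0.07 and Plk1 at 0.27. With the mean, -0.28, in place of the median the percentile was 1.9, below the central 95%. MYC targets of ribosome biogenesis had a median of -0.14 at percentile 56.5 with none of 22 called, and ranged from Fbl, on 1954 against 3956 counts, to Tfrc at 0.87. Of 22 p53 target and apoptosis genes, Cdkn1a was higher (1.31), Fas (-1.30) and Phlda3 (-1.11) were lower and 19 were neither, with a median of -0.09 at percentile 56.7.

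Glycolysis genes had a median of 0.21 at percentile 98.7, with 2 of 19 higher, 1 lower and 16 neither. Hk2, a hexokinase, was higher at 2.03 (1.92 to 2.13) and the lactate transporter gene Slc16a3 at 1.54, while Pgk1 was lower at -1.22. Gapdh had 82 and 99 counts, far under the level usual for this gene, and it and Pgk1 have many processed copies in the genome, so their values are uncertain. The percentile of glycolysis genes was 81.9 with the mean. Sterol synthesis genes had a median of 0.15 at percentile 96.5, with Nsdhl (1.53) and Hmgcs1 (1.20) among the higher genes and 15 of 18 neither.

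NF-kappaB target genes had a median of 0.38 at percentile 98.5, with 5 of 18 higher and none lower. Bcl3 (2.13), Bcl2a1b (1.97), Icam1 (1.55), Tnf (1.47) and Ccl5 (1.19) were higher, and the inhibitor genes Nfkbia and Tnip1 were at -0.43 and -0.51. With the mean, 0.65, the percentile was 96.7, inside the central 95%. Bcl2a1b has near-identical copies, so its value is uncertain. Granulocyte and monocyte markers (median 1.04) and NK markers (median 1.61, a list that also holds Ccl5) were higher beside these genes. Immediate-early and heat shock genes had a median of 0.67 at percentile 100 after rounding, with 6 of 21 higher and 1 lower. Atf3 was highest at 3.63 (3.22 to 4.09), followed by Fosl2 (2.07), Junb (1.36), Nr4a1 (1.20), Ier3 (1.18) and Egr2 (1.15), and Fosb was lower at -1.94 on 29 against 114 counts. Interferon-stimulated genes had a median of 0.13 at percentile 88.1 and a mean of the other sign, -0.26. Of 28 genes 2 were higher, Ifi27l2a (2.06) and Gbp3 (1.33), and 2 were lower, Mx1 (-4.92 on 8 against 261 counts) and Mx2 (-4.44 on 25 against 560 counts).

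Markers of other cell types moved with these groups. Granulocyte and monocyte genes had a median of 1.04 at percentile 100, with 18 of 30 higher and none lower. Macrophage genes were among the higher ones, such as Marco (2.43), C1qc (1.79; 6025 against 1762 counts) and Csf1r (1.46), as were Cd14 (2.18) and Mpo (1.07), while the abundant neutrophil genes Ngp and S100a8 were at -0.09 and 0.29. Erythroid genes had a median of 0.55 at percentile 100, with 4 of 18 higher and none lower: Alas2 (1.33), Hba-a1 (1.27), Epb4.2 (1.27) and Hba-a2 (1.11), where the alpha globin copies share reads. Of 12 NK and cytotoxic cell genes, 7 were higher, among them Fasl (2.87) and Prf1 (2.27), and the median was 1.61 at percentile 100; Gzma was at -0.29. Megakaryocyte genes had a median of 0.98 at percentile 99.4, with 5 of 12 higher, among them Ppbp (2.66) and Pf4 (1.96). Stromal and endothelial genes had a median of 1.13 at percentile 100, with 8 of 19 higher, among them Cxcl12 (2.92; 1857 against 249 counts) and Lepr (1.42), and with Pdgfrb lower at -1.48.

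B cell and antigen-presenting cell genes lay within their random lists. Of 16 B cell genes none was higher and 2 were lower, Spib (-3.01) and Pax5 (-2.04), with a median of -0.02 at percentile 38.2; this median was 0.06 with TMM and 0.05 with the median of ratios, so that it has no fixed sign. Antigen-presenting cell genes had a median of -0.13 at percentile 31.1, and of 15 genes Siglech was higher at 1.09 on 91 against 43 counts and none was lower. When the genes of all of these cell type lists were left out, 1508 genes were higher and 738 lower.

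Lists of RNA classes also differed in part. Replication-dependent histone genes, whose messages mostly lack a poly(A) tail, had a median of 0.98 at percentile 100, with 22 of 58 higher and none lower, among them Hist1h2an (1.95) and Hist1h2bc (1.91; 3305 against 890 counts). With a pseudocount of 5, the calls of 4 of these genes ended (Hist1h4d, Hist1h2ah, Hist1h2al and Hist1h3g). Histone genes are near-identical to each other, so single values are uncertain. The other RNAs without a tail or kept in the nucleus had a median of 0.05 at percentile 57.7, with U11 (2.03) and U12 (2.08) higher, 7SK at -0.05, Malat1 at -0.37 and 6 of 8 neither. Transcripts of the mitochondrial genome made up 32.2% of the counts in the knockout pool and 29.2% in the wild-type pool; the median of 35 genes was 0.06 at percentile 97.3, with none called. Ribosomal protein genes formed the list that lay below its random lists, with a median of -0.23 at percentile 1.83. Of its 94 genes 3 were higher, Rps6ka6 (5.55), Rpl29 (2.36) and Rps4y2 (2.01), 1 was lower, Rpl3l (-3.50), and 90 were neither. The name pattern of this list also took kinase genes such as Rps6ka6; without them 84 genes had a median of -0.26 at percentile 0.60. With the mean of all 94, -0.12, the percentile was 9.01, inside the central 95%, and many of these genes share reads with processed copies.

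**Figure D3:**
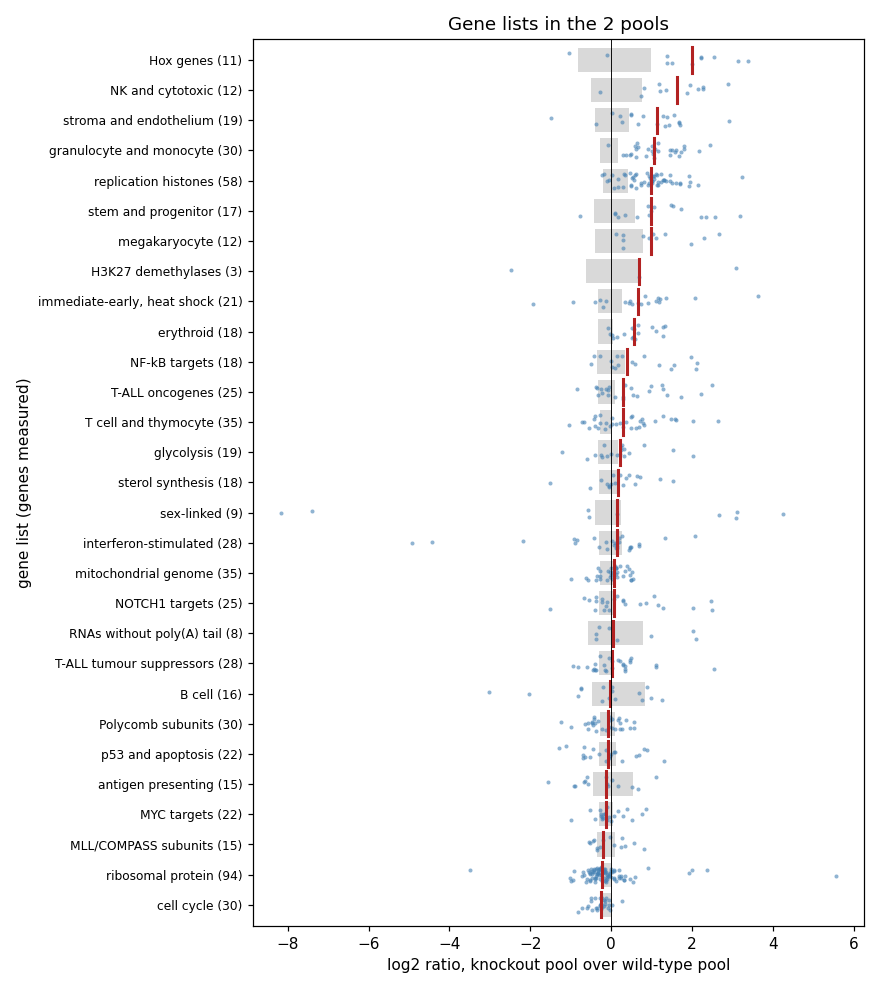
Log2 ratio of the knockout pool over the wild-type pool for the measured genes of 29 lists (points), with each list's median (red line) and the central 95% of the medians of 10000 random lists matched in size and expression (grey bar). Hox, NK, stromal and granulocyte and monocyte genes had the highest medians, from 1.99 to 1.04, and cell cycle genes the lowest at -0.26.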

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

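The depth without mitochondrial and erythroid genes, the calls without sex-chromosome genes and T cell receptor segments, the list without kinases and the chromosome settings were chosen after the data were seen; the other settings were planned. No paired analysis was possible because the counts are pooled by genotype and carry no replicate number; for the same reason the DESeq2 fit and the leaving out of samples were not run. The numbers of genes higher and lower by 2-fold moved with the filters that set them: they were 2718 and 1973 with no count filter, 840 and 372 with a combined count of at least 500, and 2617 and 2037 with a 1.5-fold minimum, since more or fewer genes can pass. In the authors' deposited table they were 5057 and 6387 with no fold minimum and 2770 and 2072 with no count filter. Scaling moved them less, from 1548 and 743 with the upper quartile to 1732 and 640 with the depth that leaves out mitochondrial and erythroid genes, and the share of higher genes went from 67.6% to 73.0%. The scalings moved the median of all genes by at most 0.093 on the log2 scale. The ratio of Kdm6a lay between -2.48 and -2.40 under TMM, median of ratios and upper quartile scaling and a pseudocount of 5. The number of lists above their random lists was 14 in each setting but the mean, where it was 11 and the demethylase, NF-kappaB and glycolysis lists were no longer above; with members of at least 100 counts the Hox list was no longer above and the mitochondrial list was. With the mean, the 1 list below was cell cycle in place of ribosomal protein. The causes were not tested. Of the values of single named genes under the scalings and the pseudocount, 467 stayed within their counting interval and 77 left it. The list values were also taken with the mean, the higher count minimum and the list without kinases. Of these, 125 stayed within an interval of the list median from simulated binomial counts and 50 left it. No called value changed sign. Depth limits genes near 100 combined counts, and the missing spread between tumours limits every result.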

Other observations

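The tests on chromosome windows, on the cell type lists and on histone genes were chosen only after the result was seen. So were the genes first named in this part, while others, such as Trbv15 and H19, had been picked by the planned rules. The tests of expression and GC content and of the lower quartile were set before their result was seen.

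Each pool was led by a different T cell receptor beta segment. Trbv15 held 58956 of the 74763 counts of Trbv segments in the wild-type pool, 78.9% (exact 95% interval 78.6 to 79.2), and 3.14% of the 36595 in the knockout pool. In the knockout pool Trbv5 held 55.1% (54.6 to 55.6), against 0.30% in the wild-type pool. Of the gamma segments Tcrg-V4 had 1555 counts in the knockout pool and 84 in the wild-type pool, and the delta segment Trdv1 had 133 and 6735. The constant gene Trbc2 was lower in the knockout pool (log2 ratio -1.19) and Trbc1 higher (1.05).

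Both genes of the imprinted Igf2 and H19 locus were higher in the knockout pool. Igf2, a fetal growth factor, had 2697 counts against 49 (log2 ratio 5.79, 5.40 to 6.24) and H19, its neighbour on chromosome 7, had 7233 against 72. Grb10, another imprinted gene, had 784 against 37 counts (4.41) and Hmga2 had 303 against 19 (3.98). The imprinted gene Dlk1 went the other way at -3.22 on 18 against 175 counts, as did the RNA-binding protein gene Igf2bp3 at -1.16. The extracellular matrix genes Col14a1, Nid2 and Lamc1 were higher, at 5.47, 5.70 and 4.68. Markers of stromal and endothelial cells, which also express such genes, moved the same way, with a median of 1.13, 8 of 19 higher and Cxcl12 at 2.92. Pdgfrb and the collagen gene Col1a2 of that list went the other way, at -1.48 and -0.37. The stromal median was far smaller than the log2 ratios of Igf2, H19 and these matrix genes, and a stromal source was not tested.

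Genes along chromosome 15 were slightly higher in the knockout pool, where the median log2 ratio of its 509 genes was 0.19, against -0.08 for 12615 genes of the other autosomes, a difference of 0.27 (95% bootstrap over genes 0.21 to 0.34); the differences of the other autosomes lay between -0.08 and 0.07. A few strong genes are argued against, since 12 of 12 windows along the chromosome had medians above that of the other autosomes. Expression level or GC content as the whole cause is argued against by the size of the shift, since random autosomal lists matched on both had a central 95% that ended at -0.04; percentile 100 alone says less, as 8 of the 18 other autosomes also lay outside the central 95% of lists matched on expression. The lower quartile was shifted by 0.25 (0.17 to 0.31) and the upper by 0.30. An extra copy of chromosome 15 in part of the knockout cells would give up to 0.58, for 3 copies over 2. Any broad shift of the chromosome would pass this test, so it says little on the cause. An extra copy remains a hypothesis: a lower copy number in the wild-type cells would give the same ratio. The tumours carrying it are not known and no DNA was examined.

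Markers of myeloid, NK, megakaryocyte and stromal cells were higher in the knockout pool. If a lower share of leukaemia cells raised every other cell type alike, the myeloid and B cell list medians would be close. They differed by 1.07 (95% bootstrap over genes 0.37 to 1.78). This cannot decide on a lower share, since cell types need not rise alike. The B cell genes also went both ways, with 8 above and 8 below 0. A different mix of marrow and spleen libraries cannot be told apart from the genotype, since the libraries pooled are not known. For 9 macrophage genes the median was 1.59 and for 11 neutrophil genes 0.59, a difference of 1.00 (0.73 to 1.30). A change of donor-derived myeloid cells themselves with Utx stays open and was not tested. The genotypes differed in the transplanted progenitors, so this does not extend to stromal cells of the recipients.

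Replication-dependent histone genes were higher in the knockout pool, with a median of 0.98 (95% bootstrap over genes 0.78 to 1.09) and 54 of 58 above 0. A higher share of cycling cells in the knockout pool is argued against, for these pools only. The cell cycle list had a median of -0.26 (-0.35 to -0.19), with 28 of 30 genes below 0, and -0.18 with TMM. That median lay within its random lists, at percentile 6.9, and the interval holds no spread between tumours. More RNA without a poly(A) tail in the knockout libraries cannot be told apart from an effect of genotype: the 8 other RNAs without a tail or kept in the nucleus had a median of 0.048 with an interval of -0.37 to 2.03, too wide to decide. An effect of Utx on histone messages stays open and was not tested.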
